A study of Homo sapiens with 16 samples.

How the data were processed

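Gene expression was measured in 4 human lung adenocarcinoma cell lines: PC9 and H2030, and a brain-metastatic derivative of each, PC9-BrM3 and H2030-BrM3. Per the labels' protocols, subconfluent cells grown in RPMI were held overnight in 0.2% serum and then left untreated or given Wnt3A for 3 hours. Total RNA was purified on columns and biotinylated cRNA was hybridised to Affymetrix human gene expression arrays, per the labels' protocols. Each of the 8 groups (4 lines, with and without Wnt3A) had 2 arrays, 16 in all. Group and replicate number were taken from the sample titles. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

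The values analysed were one intensity per probe set and array, deposited by the authors as positive, linear signals. The signals were made with MAS5, per the submitters' processing notes, and its version is not given in the sources used here. A check of the values showed that the mean signal was 500 on every array once 2% of probe sets were trimmed at each end, so one scaling factor per array had been applied, and genes had not been centred. The table held 22277 probe sets, of which 62 were array controls. Of the other 22215, 19064 had 1 gene symbol in the platform annotation, 1043 had several and 2108 had none. Probe sets with several symbols or none were tested but not named. Updating through Entrez gene identifiers changed 0 symbols. No table column lacked a sample, and none of the 120 pairs of arrays held identical values.

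Signals were kept on their deposited scale and converted to log2(signal + 16). A fold change given here is on that scale, which understates changes of dim probe sets. A probe set was tested if it reached its array's 40th percentile on at least 2 of the 16 arrays. This left 15417 probe sets, 13709 of them with 1 gene, for 9101 genes. Each gene was represented by its tested probe set with the highest mean over the 16 arrays. Differences were tested with limma 3.58.1 in R 4.3.3. One linear model with 8 group means was fitted to the 16 arrays, which left 8 residual degrees of freedom, and variances were moderated with an intensity trend (6 prior degrees of freedom). Values with ± are standard errors (SE) of that fit unless SD is written. Benjamini-Hochberg adjustment was applied within each comparison, with a threshold of 0.05. For arrays, precision is limited by their number, here 2 per group.

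The comparisons were the Wnt3A response in each line and as the mean of the 4 lines, each BrM3 line against its parent without Wnt3A, the mean of and the difference between those contrasts, the difference of the Wnt3A response between BrM3 and parental lines and between H2030 and PC9 lines, and untreated H2030 against PC9. The main comparisons were the mean Wnt3A response and the contrasts of each BrM3 line with its parent. In these, the genes named were the 10 largest rises and the 10 largest falls past the threshold whose arrays did not overlap between groups. For the mean Wnt3A response, the same sign in all 4 lines was required in place of that. In the other comparisons they were the 5 largest each way. Up to 4 members with the smallest p were added from each gene list described, and 9 genes tied to Wnt signalling or metastasis were to be given always. Of those 9, 6 were tested (LEF1, MYC, CCND1, DKK1, CD44 and CTNNB1). HOXB9 had a probe set with signals of 15.5 to 60.3 that the filter removed, and the others are not analysed here.

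Gene lists were tested with camera in limma on the 9101 representative probe sets, with a preset inter-gene correlation of 0.01, and again with a correlation estimated per list. The 22 lists were Wnt/TCF target genes, Wnt pathway components, HOX genes, immediate-early genes, ERK feedback and output genes, metastasis-associated genes, mesenchymal genes, epithelial genes, lung epithelial lineage genes, hypoxia and glycolysis genes, mitotic genes, G1/S and replication genes, interferon response genes, NF-kB and chemokine genes, TGF-beta and BMP response genes, cholesterol synthesis genes, amino acid and ER stress genes, p53 target genes, and markers of fibroblasts, leukocytes, endothelium and neural or glial cells. They held 740 symbols, of which 653 had a probe set of 1 gene and 554 were tested. A list needed at least 5 tested genes.

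The groups, tests, lists, naming rule and alternatives were fixed before the data were examined. The alternatives were pseudocounts of 1 and 64, quantile normalization, median centring, no filter and a stricter filter on dim probe sets, eBayes without the trend or with robust moderation, array weights, the replicate number as a block (over all arrays or within each line), one probe set per gene, only the arrays of the comparison in the fit, the mean of the BrM3 contrasts with and without Wnt3A, each of the 16 arrays left out in turn, and the estimated correlation and fry for lists. Counts without the array H2030-BrM3 replicate 2 at a 2-fold threshold, and the overlap of calls without it, were chosen after seeing the data.

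The fit was tested on simulated data built from the real probe sets, with 200 of 15417 changed by known amounts. For the mean Wnt3A response it recovered 74.6% of changes of 0.5 (log2), 98.5% of changes of 1 and 100% of changes of 2, with 9 false calls among 191. For the Wnt3A response in H2030-BrM3 these shares were 20.9%, 68.7% and 95.5%, with 4 false calls among 127. For PC9-BrM3 against PC9 they were 28.4%, 71.6% and 95.5%, with 6 false calls among 136. The simulation gave every group the same spread, while the real untreated H2030-BrM3 replicates correlated least (0.9788). The shares and false calls for H2030-BrM3 may therefore not hold in the real data. A list of 35 genes raised by 0.3 (log2) was called and 0 of 21 other lists were. Simulated genes varied independently of each other, so this does not show how often lists are called wrongly where genes are correlated.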

Results

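The data were 16 arrays from 4 human lung adenocarcinoma lines, 2 per line and treatment. PC9 and H2030 are parental lines, and each BrM3 line is a derivative of its parent selected in mice for brain metastasis. Cells had been held overnight in low serum and were measured without Wnt3A or after 3 hours of Wnt3A, a secreted ligand that activates beta-catenin signalling. Across the 16 arrays the median signal ranged from 112.6 to 124.5, the 40th percentile from 55.2 to 68.68 and the highest signal from 15479 to 20549. Replicates of a group correlated at 0.9788 to 0.9913 across probe sets, and arrays of different lines at 0.9659 at most. The lowest replicate correlation was that of untreated H2030-BrM3. Its replicate 2 had a GAPDH 3'/5' signal ratio of 1.24, against 0.921 to 1.01 on the other 15 arrays.

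The first comparison asked which genes responded to 3 hours of Wnt3A whatever the line, as the mean of the 4 within-line differences (4 lines, n = 2 arrays per group). DKK1, a secreted Wnt antagonist and Wnt target, rose 2.04-fold (log2 fold change 1.03 ± 0.04, adjusted p = 9.96e-09). BMP4, a bone morphogenetic protein ligand, rose 2.6-fold (1.38 ± 0.14, adjusted p = 0.000176), and EDN1, the precursor of the vasoactive peptide endothelin-1, rose 1.98-fold (0.98 ± 0.09, adjusted p = 4.82e-05). CXCL8, the chemokine interleukin-8, rose 1.54-fold (0.62 ± 0.07, adjusted p = 0.000973). All 4 had higher mean signals with Wnt3A in 4 of 4 lines, but BMP4 in H2030 lay near background (7.7 ± 1.59 and 9.71 ± 1.03, SD) and CXCL8 in H2030-BrM3 differed by less than its replicates (732 ± 145 and 798 ± 160). The matricellular genes CCN2 and CCN1 fell in the mean of the 4 lines, CCN2 by a log2 fold change of -0.41 ± 0.06 (adjusted p = 0.00418) and CCN1 by -0.32 ± 0.04 (adjusted p = 0.00125).

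**Figure D1:**
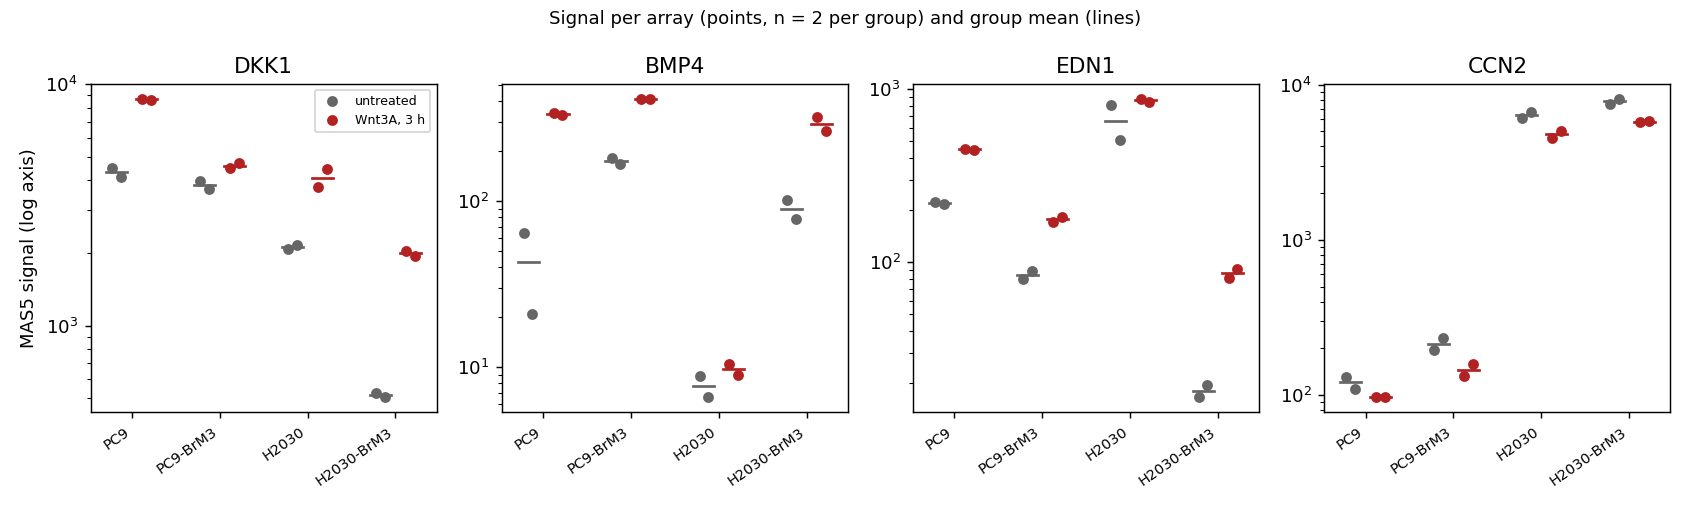
MAS5 signals (log axis) of DKK1, BMP4, EDN1 and CCN2 on each of the 16 arrays, by line, without and with Wnt3A; points are arrays and bars are means of 2. The mean DKK1 signal in H2030-BrM3 went from 516 to 1990 with Wnt3A, and that of CCN2 in H2030 from 6400 to 4810.

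In all, 39 probe sets were called in the mean response, 31 higher and 8 lower, for 18 genes that rose and 7 that fell. An unadjusted p under 0.05 was found at 1194. Without any response, a share of 0.05 of the 15417 tested is expected to have such a p. Counts of unadjusted p-values, here and below, are therefore not counts of responding probe sets. Far more probe sets were called in the mean response without H2030-BrM3 replicate 1. That fit left replicate 2, the array with the high GAPDH ratio, as the only untreated array of its line. In those calls the deviation of that array cannot be told apart from a Wnt3A response. Other genes with the same sign in all 4 lines that rose included AURKC, an aurora kinase (0.58, adjusted p = 0.0213), RESF1 (0.48, adjusted p = 0.00814), ARHGAP12 (0.47, adjusted p = 0.00668), the pseudokinase TRIB2 (0.45, adjusted p = 0.00814), TMEM51 (0.38, adjusted p = 0.027) and the insulin receptor substrate IRS1 (0.34, adjusted p = 0.00498). Those that fell included the epithelial ETS factor ELF3 (-0.39, adjusted p = 0.00869), the NF-kB-inducing kinase MAP3K14 (-0.37, adjusted p = 0.0155) and the small Maf factor MAFF (-0.33, adjusted p = 0.00814; -0.01 at its other probe set). The glucose transporter gene SLC2A3 rose in the mean (0.43, adjusted p = 0.00896), with 0.63 and 0.65 at its other probe sets and -0.03 at this probe set in H2030. PMAIP1, which encodes the BH3-only protein NOXA, rose (0.32, adjusted p = 0.0192), and the transcription factor CEBPB fell (-0.25, adjusted p = 0.0154). Of the genes to be given always, LEF1 (0.50 ± 0.14, adjusted p = 0.331), CCND1 (0.35, adjusted p = 0.574), MYC (0.09, adjusted p = 0.649), CD44 (0.01, adjusted p = 0.986) and CTNNB1 (-0.01, adjusted p = 0.986) did not pass. LEF1 was dim, with group means of 2.35 to 138. Leaving out 1 array ended the calls of AURKC (11 arrays, adjusted p 0.057 to 0.086; kept without PC9-BrM3 replicate 2, H2030 replicate 1, either untreated H2030-BrM3 array or treated H2030-BrM3 replicate 1), TMEM51 (11 arrays, 0.0596 to 0.111; kept without PC9 replicate 1, treated replicate 2 of PC9-BrM3 or H2030, or either untreated H2030-BrM3 array) and PMAIP1 (11 arrays, 0.0547 to 0.0837; kept without H2030 replicate 2 or any H2030-BrM3 array). It also ended those of MAP3K14 (PC9 replicate 2, 0.06; treated PC9 replicate 2, 0.0632; PC9-BrM3 replicate 1, 0.062; treated PC9-BrM3 replicate 2, 0.0617; H2030 replicate 1, 0.052; treated H2030 replicate 1, 0.0613) and CEBPB (PC9 replicate 1, 0.0513; treated PC9 replicate 1, 0.0679; PC9-BrM3 replicate 1, 0.0643; treated PC9-BrM3 replicate 2, 0.0613; treated H2030 replicate 2, 0.0585).

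Among gene lists, Wnt/TCF target genes shifted upward in the mean response (camera, adjusted p = 0.000191, and adjusted p = 0.0234 with an estimated correlation). Of 35 tested, 3 rose (DKK1, BMP4 and EDN1), 0 fell and 32 did not pass in limma; adjusted over the list alone, 8 rose and 2 fell. RNF43, a ubiquitin ligase that removes Wnt receptors, had 0.44 (adjusted p = 0.0644). Immediate-early genes, which respond within minutes to growth factors, shifted downward (adjusted p = 0.0167, and adjusted p = 0.141 with an estimated correlation). Of 36, SGK1, a serum- and glucocorticoid-regulated kinase, rose (0.43, adjusted p = 0.00733), CCN1, CCN2 and MAFF fell, and 32 did not pass; adjusted over the list alone, 2 rose and 10 fell. SGK1 did not share a sign across lines, with 0.99 in PC9 and -0.32 in H2030. Mitotic genes also shifted downward (adjusted p = 0.0222, and adjusted p = 0.641 with an estimated correlation), although 0 of 39 passed singly in limma or adjusted over the list alone; CENPF had -0.20 (adjusted p = 0.331) and ASPM -0.15 (adjusted p = 0.51). The immediate-early call ended without H2030-BrM3 replicate 1 (adjusted p = 0.106) or treated H2030-BrM3 replicate 2 (0.0631). The mitotic call ended with fry (0.314), with quantile normalization (0.111) and without any of PC9 replicate 2 (0.0563), treated PC9 replicate 2 (0.0624), PC9-BrM3 replicate 1 (0.103), treated PC9-BrM3 replicate 1 (0.105), H2030 replicate 2 (0.148), treated H2030 replicate 1 (0.3), H2030-BrM3 replicate 1 (0.23) or treated H2030-BrM3 replicate 2 (0.0631). The other 19 lists were not called (adjusted p 0.147 to 0.972). Among them, Wnt pathway components (0.972) and lung epithelial lineage, mesenchymal, endothelial and fibroblast genes had 0 members past the threshold.

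The Wnt3A response was next taken line by line, with 2 treated and 2 untreated arrays each. In PC9, DKK1 signal went from 4320 ± 257 to 8670 ± 60 (SD, n = 2; log2 fold change 1.00, adjusted p = 0.000149). BMP4 rose from 42.8 ± 30.8 to 333 ± 4.56 (2.68 ± 0.27, adjusted p = 0.000432), SGK1 rose by 0.99 ± 0.13 (adjusted p = 0.00408), EDN1 by 0.99 ± 0.17 (adjusted p = 0.0436) and RRP1, a gene of ribosomal RNA processing, by 0.98 (adjusted p = 0.0283). Of 4 genes that fell, 3 were TNC, which encodes the matrix protein tenascin-C (-0.93 ± 0.15, adjusted p = 0.0282), DDIT4, a stress-induced inhibitor of mTORC1 (-0.76 ± 0.10, adjusted p = 0.00581), and CCN1 (-0.57 ± 0.08, adjusted p = 0.00616). Together 21 probe sets were called, 17 higher and 4 lower, with 1008 at an unadjusted p under 0.05. Fewer were called without the eBayes trend, with only the PC9 arrays in the fit or with a replicate block within line. More were called with array weights. No list was called (adjusted p 0.0948 to 0.972). LEF1 had 0.84 (adjusted p = 0.514). Without PC9 replicate 1 the calls of CCN1 (0.107), DDIT4 (0.0992), SGK1 (0.0506), RRP1 (0.213), TNC (0.114) and EDN1 (0.174) ended; without treated replicate 1 those of CCN1 (0.127), RRP1 (0.28), TNC (0.28) and EDN1 (0.282); without treated replicate 2 those of these 4 genes (0.0501, 0.156, 0.0976 and 0.307), DDIT4 (0.113) and SGK1 (0.0882). Without replicate 2, TNC (0.142) and EDN1 (0.172) lost theirs, and arrays of other lines ended those of EDN1 (each PC9-BrM3 array and each treated H2030 or H2030-BrM3 array, 0.0642 to 0.0982), RRP1 (both treated H2030, up to 0.0615) and TNC (both treated PC9-BrM3, up to 0.0506).

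In PC9-BrM3, DKK1 signal was 3820 ± 201 without and 4600 ± 131 with Wnt3A (SD, n = 2; log2 fold change 0.27, not called). Only 4 probe sets were called in this line, 3 higher and 1 lower, and their genes were chosen after their values were seen. An unadjusted p under 0.05 was found at 621, less than the share of 0.05 of the 15417 tested that is expected without any response. With only the arrays of this line in the fit, or with 1 probe set per gene, 0 were called. SLC2A3 rose by 0.80 ± 0.09 (adjusted p = 0.0041), although its brightest probe set, at 0.61, did not pass (adjusted p = 0.448). STC1, which encodes the glycoprotein hormone stanniocalcin-1, rose by 1.21 ± 0.17 (adjusted p = 0.0305) at one probe set, while its other probe sets had -0.22 and -0.28. The forkhead gene FOXN3 fell by 1.54 ± 0.23 (adjusted p = 0.0346) at one probe set, with 0.13 and -0.57 at the others. The other called probe set, at 0.90, carried the symbols of 2 genes, SLC2A3 among them. SLC2A3 lost its call without PC9-BrM3 replicate 2 (0.107) or treated replicate 1 (0.068). STC1 lost its call without PC9 replicate 1, PC9-BrM3 replicate 1 or 2, treated PC9-BrM3 replicate 1 or any treated H2030 or H2030-BrM3 array (0.0514 to 0.339), and FOXN3 without any array but the treated PC9 arrays, PC9-BrM3 replicate 2 and the untreated H2030-BrM3 arrays (0.0541 to 0.315). NF-kB and chemokine genes shifted upward (adjusted p = 0.00281, and adjusted p = 0.144 with an estimated correlation) with 0 of 27 past the threshold in limma and 1 higher adjusted over the list alone. Amino acid and ER stress genes did likewise (adjusted p = 0.0456, and adjusted p = 0.144 with an estimated correlation), with 0 of 34 either way. The first list's call ended without PC9-BrM3 replicate 1 (0.0862) and the second's without any of the 4 PC9-BrM3 arrays or either treated PC9 array (0.0561 to 0.345) and with quantile normalization (0.239), and both ended with fry (0.216).

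In H2030, DKK1 signal went from 2120 ± 46 to 4090 ± 488 (SD, n = 2; 0.94 ± 0.08, adjusted p = 0.000351), while BMP4 stayed near background at 7.7 and 9.71 (0.12, adjusted p = 0.999). EDN1 had 658 ± 211 and 864 ± 28.6 (0.42, adjusted p = 0.957). TINAGL1, which encodes a matrix protein, rose from 16.3 ± 3.61 to 96.8 ± 26.3 (1.79 ± 0.24, adjusted p = 0.0244). These 2 probe sets, DKK1 and TINAGL1, were the only ones called in limma. An unadjusted p under 0.05 was found at 744, again less than a share of 0.05 of the 15417 tested. With only the H2030 arrays in the fit 0 probe sets were called, so neither DKK1 (limma adjusted p = 0.112) nor TINAGL1 passed. TINAGL1 did not pass without H2030 replicate 1 (0.0845) or 2 (0.0776), treated replicate 1 (0.247) or any PC9-BrM3 array (0.0562 to 0.0659). Of the lists, Wnt/TCF target genes shifted upward (adjusted p = 0.00446, and adjusted p = 0.059 with an estimated correlation), with DKK1 the 1 member of 35 that rose and 3 higher adjusted over the list alone. HOX genes, which encode body-axis homeobox factors, shifted upward with 0 of 16 past the threshold (adjusted p = 0.00446, and adjusted p = 0.223 with an estimated correlation). Immediate-early genes shifted downward (adjusted p = 0.00368, and adjusted p = 0.059 with an estimated correlation; 0 of 36 passed, 3 lower adjusted over the list alone). Hypoxia and glycolysis genes (adjusted p = 0.0287, and adjusted p = 0.1 with an estimated correlation; 0 of 35) and mitotic genes (adjusted p = 0.0254, and adjusted p = 0.496 with an estimated correlation; 0 of 39) also shifted downward. Without H2030 replicate 2 the HOX (0.234), immediate-early (0.064), hypoxia (0.216) and mitotic (0.494) calls ended, without replicate 1 the Wnt/TCF and hypoxia calls (both 0.0675), and without treated replicate 2 the hypoxia call (0.0974); with fry the HOX (0.173), hypoxia (0.0698) and mitotic (0.433) calls ended. Without treated replicate 1 the mitotic list turned upward (0.923).

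In H2030-BrM3, DKK1 signal went from 516 ± 16.2 to 1990 ± 60.9 (SD, n = 2; 1.91 ± 0.08, adjusted p = 2.77e-08) and EDN1 from 18 ± 2.14 to 86.4 ± 7 (1.59 ± 0.17, adjusted p = 0.00209). BMP4 rose from 89.8 ± 16.7 to 291 ± 41.5 (1.54 ± 0.27, adjusted p = 0.0344). The ATP-gated channel gene P2RX5 rose by 1.28 (adjusted p = 0.00989) and SCNN1A, a subunit of the epithelial sodium channel, by 1.07 (adjusted p = 0.0167; -0.07 at its other probe set), the latter between signals of 8.13 and 34.7 that lie below every array's 40th percentile. Of 8 genes that fell, the largest falls were in the olfactory receptor OR1F1 (-1.55, adjusted p = 0.00989), the ubiquitin ligase TRIM38 (-1.04, adjusted p = 0.0131; 0.08 at each of 2 other probe sets), MAFF (-0.70, adjusted p = 0.00989), MAP3K14 (-0.67, adjusted p = 0.0348) and the histone gene H2BC5 (-0.63, adjusted p = 0.013). OR1F1 was dim, with a mean log2(signal + 16) of 6.03 over all arrays. CCND1 had 0.86 (adjusted p = 0.273), its untreated replicates being 990 and 373.5, and LEF1 had 0.89 (adjusted p = 0.266). In all 33 probe sets were called, 25 higher and 8 lower (1851 at an unadjusted p under 0.05). The count of unadjusted p-values was much lower without H2030-BrM3 replicate 2, a fit that leaves 1 untreated array of this line. The main fit pools the spread over all groups, though the untreated replicates of this line correlated least. Only 1 probe set was called with array weights, 1 with only the arrays of this line, and 12 with a replicate block within line. At most 1 of the genes named here thus stayed called in each of the first 2 fits. Without H2030-BrM3 replicate 2, the array with the high GAPDH ratio, 14 were called and 8 of them were among the 33. DKK1 (5.19e-07), EDN1 (0.00654) and TRIM38 (0.00226) stayed called without it, and BMP4 (0.2), P2RX5 (0.0579), SCNN1A (0.0902), H2BC5 (0.0561), MAP3K14 (0.205), MAFF (0.0561) and OR1F1 (0.071) did not. Without replicate 1 far more were called, but replicate 2 was then the only untreated array of this line. Its deviation cannot be told apart from a Wnt3A response in those calls. Without treated replicate 2, 12 were called, and BMP4 (0.117), H2BC5 (0.0607), MAFF (0.0825), MAP3K14 (0.146), OR1F1 (0.0566), P2RX5 (0.0628), SCNN1A (0.15) and TRIM38 (0.108) ended. Without treated replicate 1, BMP4 (0.132), H2BC5 (0.064) and MAP3K14 (0.116) ended, and arrays of other lines also ended BMP4 (all but the untreated PC9 arrays) and MAP3K14 (all 12 arrays), each up to 0.0722. Wnt/TCF target genes shifted upward (adjusted p = 0.0411, and adjusted p = 0.18 with an estimated correlation), with 3 of 35 higher, 0 lower and 7 higher adjusted over the list alone. That call ended without H2030-BrM3 replicate 1 (0.462), treated replicate 1 (0.157) or any treated array of the other lines (0.0508 to 0.0582).

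**Figure D2:**
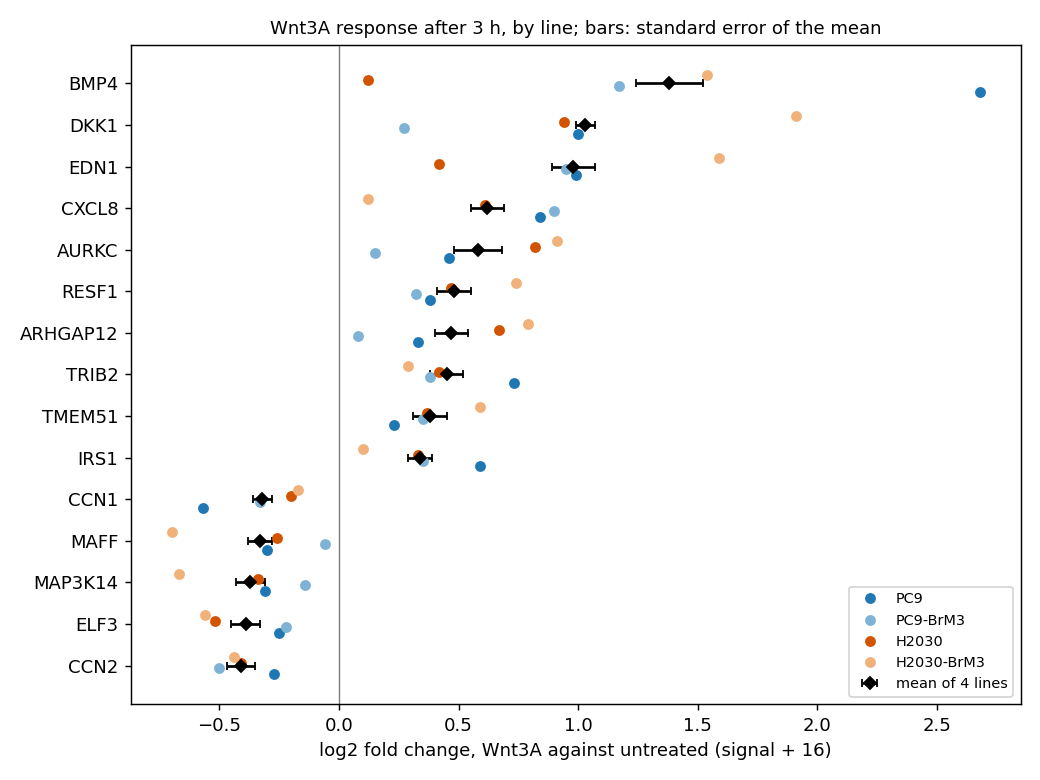
Log2 fold change with Wnt3A of 15 genes. Coloured points are the 4 lines (2 treated and 2 untreated arrays each). Black diamonds are the mean of the 4 lines, with bars for its SE. DKK1 ranges from 0.27 in PC9-BrM3 to 1.91 in H2030-BrM3, and BMP4 from 0.12 in H2030 to 2.68 in PC9.

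Whether the lines differed in their response was tested directly. Between BrM3 and parental lines, limma called 0 probe sets (995 at an unadjusted p under 0.05) and 0 of 22 lists (adjusted p 0.262 to 0.804). The DKK1 difference was 0.12 (adjusted p = 0.817), a mean of unlike pairs: its response was 1.00 in PC9 and 0.27 in PC9-BrM3, but 0.94 in H2030 and 1.91 in H2030-BrM3. The count of probe sets called between BrM3 and parental lines was far higher without H2030-BrM3 replicate 1, which left replicate 2 as the only untreated array of that line. Between H2030 and PC9 lines 2 were called. DKK1 responded more in the H2030 lines (0.79 ± 0.08, limma adjusted p = 0.003). IER3, an immediate-early gene induced by NF-kB, differed the other way (-0.50 ± 0.07, limma adjusted p = 0.0225). Its values were 0.01, 0.20, -0.27 and -0.51 in PC9, PC9-BrM3, H2030 and H2030-BrM3, the last a called fall (limma adjusted p = 0.00886). The response of NF-kB and chemokine genes was lower in the H2030 lines (camera, adjusted p = 6.72e-06, and adjusted p = 0.0622 with an estimated correlation). Of 27 members, 0 were higher and 1 lower, with 5 lower adjusted over the list alone. Moderation without the trend ended both gene calls (DKK1 0.105, IER3 0.308). IER3 also lost its call without any 1 of 12 arrays (0.0628 to 0.166), namely all but PC9 replicate 1, the untreated H2030-BrM3 arrays and treated H2030-BrM3 replicate 1. Between H2030 and PC9 lines, too, far more probe sets were called without H2030-BrM3 replicate 1, with replicate 2 as the only untreated array of that line. Across 15417 probe sets the responses of any pair of lines correlated at -0.078 to 0.138; genes are not independent replicates.

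The next comparison set untreated PC9-BrM3 against untreated PC9 (2 arrays each), the brain-metastatic derivative against its parent. The epithelial keratin KRT13 went from a signal of 41.3 ± 15.6 to 3200 ± 200 (SD, n = 2), 57.2-fold (5.84 ± 0.34, adjusted p = 4.55e-08). S100A4, a calcium-binding protein linked to cell motility, went from 260 ± 0.848 to 4450 ± 52.6, 16.2-fold (4.02 ± 0.09, adjusted p = 1.48e-12), and the receptor tyrosine kinase AXL rose 13.1-fold (3.71 ± 0.11, adjusted p = 1.06e-10). FN1, which encodes fibronectin, fell from 2710 ± 168 to 82.8 ± 62.4 (-4.95 ± 0.29, adjusted p = 5e-08). WNT5A, a ligand of non-canonical Wnt signalling, was 6.21-fold lower (-2.64 ± 0.14, adjusted p = 2.69e-08), and the membrane mucin MUC1 4.81-fold lower (-2.27 ± 0.14, adjusted p = 8.08e-08). The other largest rises were in the protease inhibitor CSTA (3.72), the calcification inhibitor MGP (3.49), the tubulin TUBB2B (3.44), the Rac GTPase-activating protein CHN1 (3.32), QPRT, an enzyme of NAD synthesis (3.03), the protease CTSE (2.88) and the keratin KRT23 (2.75). The other largest falls were in the calprotectin subunits S100A9 (-2.74) and S100A8 (-2.68), the protocadherin PCDH7 (-2.68), OLFML3 (-2.65), ARID5B (-2.42), the tubulin-modifying enzyme TTLL4 (-2.22) and the glutathione peroxidase GPX3 (-2.18). These 14 had adjusted p-values of at most 2.06e-05. In all 4159 probe sets were called, 2108 higher and 2051 lower, of which 392 rose and 297 fell by at least 2-fold. Without H2030-BrM3 replicate 1 or 2 the count was 4943 or 4936, and the lowest count without any 1 array was 2813.

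By list, G1/S and replication genes rose together in PC9-BrM3: 31 of 39 were higher, 0 lower and 8 did not pass, with 34 higher adjusted over the list alone (adjusted p = 1.27e-11, and adjusted p = 0.0476 with an estimated correlation). Examples were the replication-licensing factors CDC6 (1.51) and MCM10 (1.10), RFC3 (1.03) and thymidylate synthase TYMS (0.69). ERK feedback and output genes, transcribed downstream of MAP kinase signalling, were higher in 17 of 26 and lower in 3, and in 19 and 3 adjusted over the list alone (adjusted p = 1.03e-05, and adjusted p = 0.034 with an estimated correlation). Among them were the EGF-family ligand HBEGF (2.33), the AP-1 subunit FOSL1 (1.85), PHLDA1 (1.18) and the feedback inhibitor SPRY4 (1.02). Immediate-early genes were higher in 15 of 36 and lower in 5, and in 16 and 5 adjusted over the list alone (adjusted p = 0.00543, and adjusted p = 0.0487 with an estimated correlation), with ATF3 (1.83), CCN1 (1.62) and JUN (1.13). Amino acid and ER stress genes were higher in 18 of 34 and lower in 6, and in 19 and 7 adjusted over the list alone (adjusted p = 0.00543, and adjusted p = 0.0476 with an estimated correlation). They included asparagine synthetase ASNS (1.45), the serine-synthesis enzyme PSPH (1.16) and the alanyl-tRNA synthetase AARS1 (0.94). Wnt/TCF target genes were higher in 13 of 35 and lower in 2, also adjusted over the list alone (adjusted p = 0.015, and adjusted p = 0.0487 with an estimated correlation), with FOSL1, the zinc finger factor SNAI2 (1.63), JUN and ENC1 (0.59). Metastasis-associated genes were higher in 16 of 37 and lower in 8, also adjusted over the list alone (adjusted p = 0.0422, and adjusted p = 0.068 with an estimated correlation), with S100A4, HBEGF and the protease CTSB (0.84) higher and the adaptor NEDD9 lower (-1.08). Hypoxia and glycolysis genes fell: 16 of 35 were lower and 6 higher, 18 and 7 adjusted over the list alone (adjusted p = 0.0448, and adjusted p = 0.069 with an estimated correlation). The aldolase ALDOC (-0.85), DDIT4 (-0.82) and the mitophagy gene BNIP3 (-0.75) were lower and the enolase ENO2 higher (1.79). The metastasis call ended without PC9 replicate 2 (0.0717) or PC9-BrM3 replicate 1 (0.0593), the hypoxia call without PC9 replicate 1 (0.19) or PC9-BrM3 replicate 2 (0.106), and both without either treated PC9-BrM3 array (0.0509) or with quantile normalization (0.0572 and 0.133).

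The Wnt genes of PC9-BrM3 went in several directions. LEF1, a transcription factor of the Wnt pathway, rose (1.95 ± 0.27, limma adjusted p = 0.000117) from 24.1 ± 15.8 (SD, n = 2) in PC9. That signal lay below the 40th percentile of the arrays, so the size depends on the pseudocount (2.57 with 1, 1.17 with 64). The related factor TCF7L1 (-2.11) and the receptor FZD5 (-1.08) fell. Of 46 Wnt pathway components 4 were higher and 8 lower, also adjusted over the list alone, and the list was not called (adjusted p = 0.316). MYC rose slightly (0.26, adjusted p = 0.0388); DKK1 (-0.18, adjusted p = 0.143), CD44 (0.09, adjusted p = 0.517), CTNNB1 (0.04, adjusted p = 0.796) and CCND1 (0.49, adjusted p = 0.204) did not pass, although another CCND1 probe set did (0.63, adjusted p = 0.00126). MYC lost its call without PC9 replicate 2 (0.242), either PC9-BrM3 replicate (0.191 and 0.0795) or any treated PC9, PC9-BrM3 or H2030 array (0.0532 to 0.0536). The other lists were not called (15 in all, adjusted p 0.075 to 0.811). Among them mesenchymal genes were higher in 6 of 25 and lower in 1, with vimentin (VIM) at 1.55; fibroblast markers were lower in 1 of 12, leukocyte markers higher in 2 of 9, and endothelial markers had 0 of 5 past the threshold. The median signal of these 3 marker lists in untreated cells was 22.6, 42.1 and 17.5 in PC9 and 28.2, 37 and 25.5 in PC9-BrM3, below the 40th percentile of the arrays.

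The same comparison was made for untreated H2030-BrM3 against untreated H2030 (2 arrays each). Here the largest changes were near-complete losses of abundant transcripts. The fibrinogen chain genes FGB, FGG and FGA fell (log2 fold changes -7.89 ± 0.18, -6.94 and -6.07), FGB from a signal of 7630 ± 41 to 16.6 ± 5.91 (SD, n = 2; 236-fold, adjusted p = 3.2e-13). HTATIP2, a short-chain dehydrogenase, fell from 4120 ± 16.5 to 8.92 ± 2.9 (166-fold, adjusted p = 2.95e-14). Genes that rose included SCG2, a neuroendocrine granule protein, from 52.7 ± 23.4 to 4270 ± 826 (63.7-fold, adjusted p = 2.67e-11), and the mesenchymal cadherin CDH11 from 66.6 ± 7.19 to 4270 ± 55.9 (51.9-fold, adjusted p = 7.68e-11). S100A4 rose from 313 ± 2.65 to 1280 ± 103 (1.98, adjusted p = 3.5e-10). The other largest rises were in the LIM-domain protein TRIP6 (5.27), the glial glutamate transporter SLC1A3 (4.32), the uroplakin UPK3B (4.16), TRIB2 (4.03), the protease inhibitor SLPI (3.80), ADAMTSL3 (3.78), the neurofilament NEFL (3.72) and mesothelin, MSLN (3.67). The other largest falls were in QPRT (-6.57), which had risen in PC9-BrM3, IGFBP7 (-5.85), the endothelial protein C receptor PROCR (-5.84), the vesicle SNARE VAMP8 (-5.83), the aldo-keto reductase AKR1C2 (-5.79) and interferon-induced IFI27 (-5.41). In all 6259 probe sets were called, 3538 higher and 2721 lower, with 665 rises and 980 falls of at least 2-fold. The median log2 fold change over all probe sets tested was 0.073, against 0.015 for PC9-BrM3 against PC9. The balance of small rises and falls therefore depends on the scaling, which was kept as deposited. Far fewer were called with only the untreated H2030 and H2030-BrM3 arrays in the fit. Without H2030-BrM3 replicate 2, the array with the high GAPDH ratio, 5433 were called and each gene named for this comparison except CCND1 kept its side of the threshold.

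By list, interferon response genes fell in H2030-BrM3: 27 of 44 were lower and 1 higher, 29 and 1 adjusted over the list alone (adjusted p = 9.52e-08, and adjusted p = 0.00242 with an estimated correlation). IFI27, OAS1 (-4.31), HLA-F (-1.58) and IFI35 (-1.45) had the smallest p. NF-kB and chemokine genes were lower in 16 of 27 and higher in 1, also adjusted over the list alone (adjusted p = 4.21e-05, and adjusted p = 0.0369 with an estimated correlation), with TNFAIP8 (-2.93), the chemokine CCL2 (-2.50), TNFAIP2 (-1.53, and 0.00 at its other probe set) and IER3 (-0.96). Hypoxia and glycolysis genes were lower in 20 of 35 and higher in 5, also adjusted over the list alone (adjusted p = 0.000196, and adjusted p = 0.0138 with an estimated correlation). EPAS1, which encodes the hypoxia-inducible factor HIF-2alpha, fell 32.1-fold, and hexokinase HK1 (-2.29), the collagen-modifying enzyme PLOD2 (-1.96) and phosphofructokinase PFKP (-1.64) fell as well. Cholesterol synthesis genes were lower in 12 of 22 and higher in 2, 13 and 2 adjusted over the list alone (adjusted p = 0.00246, and adjusted p = 0.122 with an estimated correlation), with NSDHL (-1.88), IDI1 (-1.22) and TMEM97 (-0.69). TGF-beta and BMP response genes were lower in 13 of 33 and higher in 6, also adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.122 with an estimated correlation), with ID4 (-4.50), the activin subunit INHBA (-3.14), PMEPA1 (-1.39) and TGFBI (-1.35). Metastasis-associated genes were lower in 18 of 37 and higher in 10, 20 and 11 adjusted over the list alone (adjusted p = 0.037, and adjusted p = 0.0941 with an estimated correlation), with CDH11, the integrin ITGB4 (2.52) and S100A4 higher and NEDD9 lower (-1.91). Wnt/TCF target genes were lower in 16 of 35 and higher in 10, also adjusted over the list alone (adjusted p = 0.0497, and adjusted p = 0.122 with an estimated correlation), with EDN1 (-4.27), the Notch ligand JAG1 (-3.07), DKK1 (4.01-fold lower) and JUN (-1.79). Neural and glial markers, a list of another cell type, were higher in 5 of 9 and lower in 1, also adjusted over the list alone (adjusted p = 0.0464, and adjusted p = 0.122 with an estimated correlation); SLC1A3, NEFL and MAP2 (0.93) rose and ENO2 fell (-1.48). The median signal of that list was 24.8 in H2030 and 37.9 in H2030-BrM3. The Wnt/TCF call ended without any of 11 arrays, among them H2030-BrM3 replicates 1 (0.0524) and 2 (0.0814), H2030 replicate 2 (0.116) and all 8 PC9 and PC9-BrM3 arrays (up to 0.0634). The neural call ended without any of 11, among them the same 3 (0.0524, 0.0784 and 0.0722), both treated H2030-BrM3 arrays (0.0503) and 6 PC9 or PC9-BrM3 arrays (up to 0.052).

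**Figure D3:**
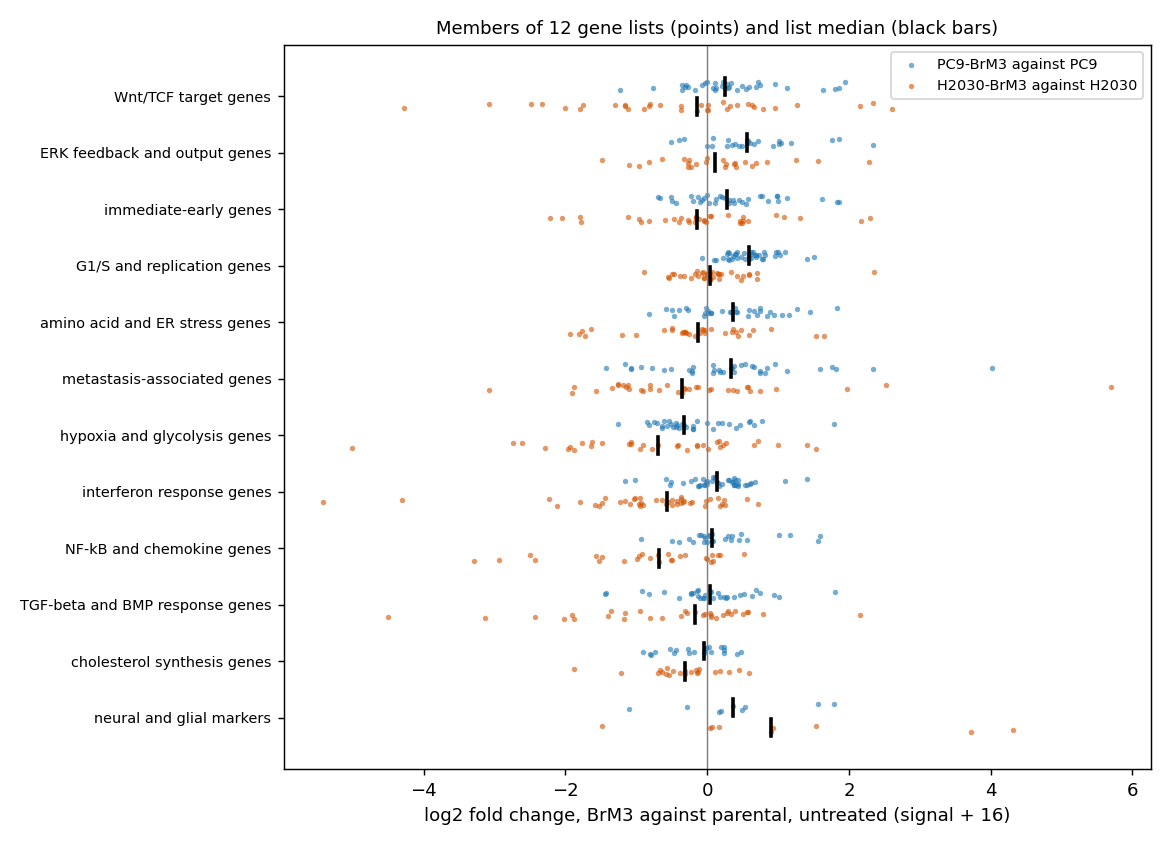
Log2 fold change of each member (points) and the median (bars) of 12 gene lists, untreated BrM3 against parental cells, for PC9 and H2030. G1/S and replication genes have 31 of 39 members called higher in PC9-BrM3, and interferon response genes 27 of 44 called lower in H2030-BrM3.

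In the Wnt genes of H2030-BrM3, LEF1 rose (1.27, adjusted p = 0.00183) from a signal of 2.35 ± 0.905 to 28.7 ± 8.61 (SD, n = 2), below the 40th percentile of the arrays in both groups. MYC rose (0.58, adjusted p = 8.51e-05) and the hyaluronan receptor CD44 fell (-1.12, adjusted p = 1.88e-07). CCND1 had 0.00 (adjusted p = 0.994) at its brightest probe set and rose at another (0.54, adjusted p = 0.00242); the former was 0.68 (adjusted p = 4.95e-05) without H2030-BrM3 replicate 2 and -0.69 (adjusted p = 3.63e-05) without replicate 1, so its direction rested on single arrays. CTNNB1 had 0.12 (adjusted p = 0.363). Of 46 Wnt pathway components 19 were higher and 7 lower, also adjusted over the list alone, and the list was not called (adjusted p = 0.527). The secreted antagonist SFRP1 (1.93) and WNT5A (1.15), which had fallen in PC9-BrM3, rose, and WNT5B (-2.12) and the receptor ROR1 (-2.57) fell. The other 13 of the 14 uncalled lists had adjusted p-values of 0.145 to 0.981; HOX genes were higher in 3 of 16 and lower in 1 and mitotic genes higher in 10 of 39 and lower in 5.

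Both derivations were then set side by side. Of the 4159 and 6259 probe sets called, 2163 were shared: 521 were higher in both and 571 lower in both, where independent lists would share 483.8 and 362. Another 1071 went opposite ways, 503 higher in PC9-BrM3 and lower in H2030-BrM3 and 568 the reverse, against 372 and 470.7 for independent lists. Across 15417 probe sets the log2 fold changes correlated at r = -0.002 (rank correlation 0.009), where genes are not independent replicates. In the mean of both, S100A4 rose 7.98-fold (3.00 ± 0.06, adjusted p = 2.34e-13), with SCG2 (3.15), SLC1A3 (2.94), UPK3B (2.60) and MSLN (2.52); FGB (-4.04), HTATIP2 (-3.76), VAMP8 (-3.12), the inhibin subunit INHBB (-3.11) and AKR1C2 (-2.98) fell. For several of these the mean came mostly from H2030-BrM3, since in PC9-BrM3 SCG2 had 0.31, FGB -0.19, HTATIP2 -0.14, VAMP8 -0.41 and AKR1C2 -0.17. LEF1 (1.61, adjusted p = 1.82e-05) and MYC (0.42) rose, DKK1 (-1.09) and CD44 (-0.52) fell, and CCND1 (0.24, adjusted p = 0.348) and CTNNB1 (0.08, adjusted p = 0.395) did not pass. The falls of DKK1 and CD44 came from H2030-BrM3 (-2 and -1.12), since they had -0.18 and 0.09 in PC9-BrM3. Another CCND1 probe set was called higher in this mean, with 0.63 in PC9-BrM3 and 0.54 in H2030-BrM3. In all 5716 probe sets were called, 3147 higher and 2569 lower. Of the lists, 8 were called, and among them only hypoxia genes were also called in each derivation alone. ERK and G1/S genes were called in PC9-BrM3 only, and the rest in H2030-BrM3 only. With an estimated correlation 3 of the 8 held. Those were ERK feedback genes upward (17 of 26 higher, 4 lower; adjusted p = 0.000503, and adjusted p = 0.0446 with an estimated correlation), hypoxia genes downward (21 of 35 lower, 3 higher; adjusted p = 8.1e-06 and 0.00881) and interferon response genes downward (19 of 44 lower, 3 higher; adjusted p = 0.000223 and 0.0118). The other 5 were G1/S genes (adjusted p = 8.1e-06, and adjusted p = 0.115 with an estimated correlation) and neural and glial markers (0.0188 and 0.111) upward, and cholesterol (0.000395 and 0.111), NF-kB (0.00589 and 0.114) and TGF-beta genes (0.025 and 0.193) downward, the latter value of each being with an estimated correlation.

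**Figure D4:**
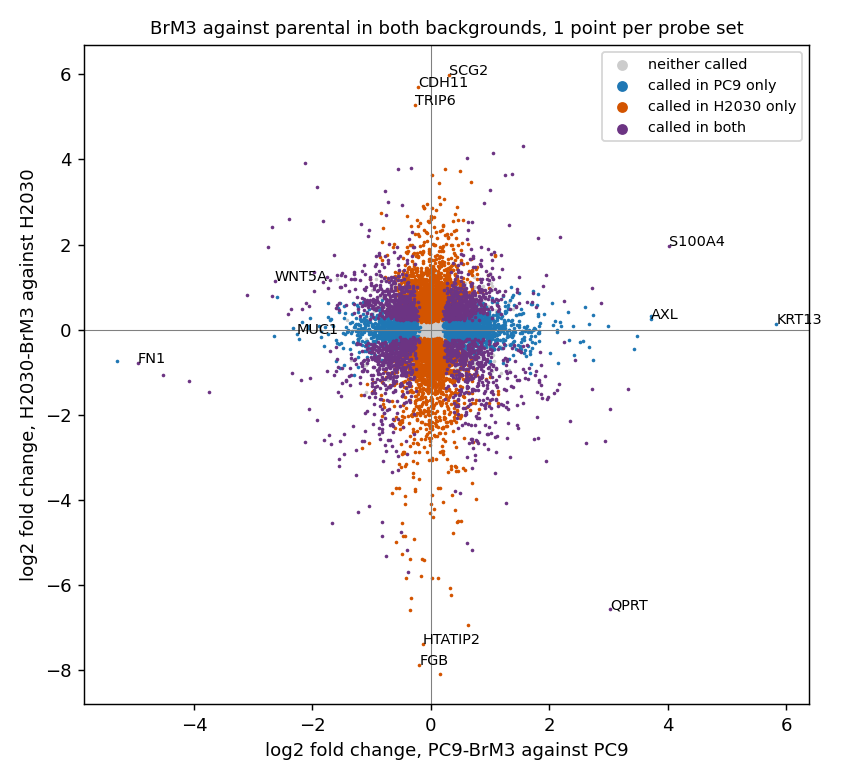
Log2 fold change of each tested probe set in H2030-BrM3 against H2030 (vertical) and PC9-BrM3 against PC9 (horizontal), untreated cells, with named genes labelled. Points spread along both axes (r = -0.002), with S100A4 at 4.02 and 1.98 and QPRT at 3.03 and -6.57.

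The difference between the derivations, PC9 minus H2030, was called at 5662 probe sets, 2610 higher and 3052 lower. QPRT had the largest difference (9.60), followed by FGB (7.69), FGG (7.57), HTATIP2 (7.24) and FGA (6.40); on the other side were CDH11 (-5.91), SCG2 (-5.68), TRIP6 (-5.55), PCDH7 (-5.11) and S100A9 (-4.68). Sizes and order depended on the pseudocount where a group was dim: with 1 and 64, QPRT had 11.72 and 7.08, FGB 8.43 and 6.5, and HTATIP2 8.59 and 5.7. DKK1 (1.83), CD44 (1.21) and MYC (-0.33, adjusted p = 0.0478) differed and LEF1 did not pass (0.68, adjusted p = 0.192). Of 22 lists, 11 were called, each relatively higher in the PC9 derivation, and 5 held with an estimated correlation: interferon response (23 of 44 higher, 2 lower; adjusted p = 4.85e-07, and adjusted p = 0.00339 with an estimated correlation), NF-kB (11 of 27 and 1; 8.54e-05 and 0.0264), metastasis-associated (22 of 37 and 7; 0.000371 and 0.0182), Wnt/TCF target (15 of 35 and 4; 0.000843 and 0.0224) and amino acid and ER stress genes (18 of 34 and 5; 0.00269 and 0.0252). The other 6 were G1/S (adjusted p = 0.00013, and adjusted p = 0.12 with an estimated correlation), TGF-beta (0.00841 and 0.105), p53 target (0.0147 and 0.0865), immediate-early (0.0209 and 0.0865), ERK (0.0453 and 0.12) and hypoxia genes (0.0489 and 0.0865). Without any array but PC9 replicate 2 and the treated H2030-BrM3 arrays MYC did not pass (0.0516 to 0.171), nor did ERK genes without PC9 replicate 1 (0.0566), PC9-BrM3 replicate 1 (0.0637), H2030 replicate 2 (0.0536) or H2030-BrM3 replicate 2 (0.0512). Hypoxia genes did not pass without PC9 replicate 2 (0.11), PC9-BrM3 replicate 1 (0.0637), H2030 replicate 2 (0.0536), H2030-BrM3 replicate 2 (0.0792) or any treated parental array (up to 0.0551).

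Last, the untreated parental lines were compared, H2030 against PC9 (2 arrays each). Epithelial genes were far lower in H2030: 30 of 35 were lower and 5 higher, also adjusted over the list alone (adjusted p = 3.34e-09, and adjusted p = 0.00643 with an estimated correlation). Keratin 19 (KRT19) had a signal of 15200 ± 535 in PC9 and 0.97 ± 0.0798 in H2030 (SD, n = 2; log2 fold change -9.81), and E-cadherin (CDH1) 4460 ± 92.9 and 5.44 ± 5.66 (-7.73). S100P (-8.31), S100A9 (-7.74) and VGLL1 (-7.68) were the other largest falls, and the chemokine CCL2 (8.38), the nicotinamide methyltransferase NNMT (8.15), FGB (7.76), the vitamin D hydroxylase CYP24A1 (7.61) and FGG (7.56) the largest rises. DKK1 (-1.02), CD44 (-1.05), CCND1 (-1.80), LEF1 (-1.07, adjusted p = 0.00351) and CTNNB1 (-0.34, adjusted p = 0.00884) were lower in H2030, and MYC did not pass (-0.13, adjusted p = 0.204). In all 9161 probe sets were called, 4571 higher and 4590 lower. Interferon response genes were higher in 27 of 44 and lower in 4 (adjusted p = 0.00111, and adjusted p = 0.0238 with an estimated correlation). Also upward were G1/S genes (30 of 39 higher, 1 lower; adjusted p = 0.000142, and adjusted p = 0.183 with an estimated correlation), NF-kB genes (20 of 27 and 3; adjusted p = 0.0007, and adjusted p = 0.0797 with an estimated correlation), mesenchymal genes (15 of 25 and 3; adjusted p = 0.0231, and adjusted p = 0.0797 with an estimated correlation) and TGF-beta genes (17 of 33 and 7; adjusted p = 0.0491, and adjusted p = 0.228 with an estimated correlation). LEF1 was -0.66 (0.0625) without PC9 replicate 1, CTNNB1 -0.22 (0.119) without PC9 replicate 2, and the TGF-beta call ended without either of PC9 replicate 2 (0.064) and H2030 replicate 1 (0.0505), without any treated array (0.0514 to 0.0594) and with quantile normalization (0.0547). The other 16 lists were not called (adjusted p 0.0928 to 0.947). No called list in any comparison had a median or mean that differed in sign from its test.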

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

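Of the tests weighed here, those of 3' bias, of both count ratios without H2030-BrM3 replicate 2, of an unrelated line and of DKK1 (3) were chosen after the result was seen, and those of mixed RNA, of PC9 RNA and of the splits before.

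The untreated H2030-BrM3 replicates correlated at 0.9788 (other groups at least 0.9876), and replicate 2 had a mean correlation with the other arrays of its line of 0.9772 (replicate 1 0.9856, lowest of the other 15 arrays 0.9843) and a GAPDH 3'/5' ratio of 1.24 (others at most 1.01). A uniform 3' bias of its RNA or cDNA would raise the ratio of ACTB too. That was 1.03, below the 1.11 to 1.22 of the other 15 arrays, which argues against such a bias. The ratio of the interferon-stimulated gene factor control, 7.44, lay within that of the others (6.24 to 13.7) and decides nothing. Since this test was chosen after these ratios were seen, it does not exclude a bias. RNA of PC9 or PC9-BrM3 mixed in at 1% or more is excluded. At 41 and 46 probe sets high in these lines, the median excess of replicate 2 over replicate 1 was 0.0261% and -0.00742% of their level. For H2030 the excess was 0.0189%, but over only 7 probe sets, so this line is less firmly tested. The design gives no biological difference between the replicates, and no biological explanation was tested.

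In the BrM3 comparisons, the H2030 derivation changed more probe sets than the PC9 derivation, a pattern that was divided into 2 parts after its values were seen: 1645 against 689 called with at least a 2-fold change (ratio 2.39), and 6259 against 4159 called in all (ratio 1.5). Without H2030-BrM3 replicate 2 the ratio of 2-fold counts was 2.23, so that array does not account for the first part, but the ratio of all calls was 1.1, so the second part may rest on it; the latter ratio was 1.31 without replicate 1. Cells or RNA of a PC9 line in the H2030-BrM3 samples are excluded as the cause, since 31 PC9-specific probe sets (median PC9 signal 3841) gained 0.131% of the PC9 level over H2030. A line unrelated to H2030 under the H2030-BrM3 name remains possible: untreated H2030-BrM3 correlated with H2030 at 0.932, between 0.83 for PC9 with H2030 and 0.969 for PC9 with PC9-BrM3. A larger change under selection in mice, the biological difference the design gives, was not tested apart from these.

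By a test of the difference between cell backgrounds, the log2 Wnt3A response of DKK1 was larger in the H2030 lines (0.79). IER3 differed the other way (-0.50), with 0.01 and 0.20 in the PC9 lines and -0.27 and -0.51 in the H2030 lines. A ceiling of the DKK1 signal does not account for the DKK1 difference, since PC9-BrM3, the line with the smallest response, reached 4600 where PC9 reached 8670. PC9 and PC9-BrM3, whose untreated levels lay within 1.13-fold, differed in response by 0.74 ± 0.12, or 6.21 standard errors. The starting level of DKK1 alone thus does not set the response within the PC9 lines. This pair cannot decide whether the low start of H2030-BrM3 (516) accounts for the difference between backgrounds, which remains possible. Without H2030-BrM3 replicate 2 the adjusted p of the DKK1 difference was 0.00534, so that array is not the cause. Within the H2030 lines the response was 0.94 and 1.91, and within the PC9 lines 1.00 and 0.27, so the test of the backgrounds averages over unlike lines.

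Splits of the treated and untreated arrays, or of BrM3 and parental arrays, gave these counts. For the mean Wnt3A response 39 probe sets were called, against 16 at most in other splits (1 of 100 splits called as many). For the BrM3 minus parental response 0 were called, a count that all 100 of 100 splits reach by construction, so they decide nothing (highest other 16). For the H2030 minus PC9 response 2 were called and 4 of 100 splits called as many; the highest other, 39, is the mean response itself, since exchanging the treatment labels in both lines of one background turns the difference into the mean. For the mean of both BrM3 contrasts 5716 were called, 1 of 18 splits called as many (highest other 5662), and for their difference 5662 were called, with 2 of 18 as many (highest other 5716). Each of these highest counts is the other contrast, by the same exchange of labels, and 18 splits are too few for a share under 0.05.

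Of 109 genes named in a BrM3 comparison, 100 differed between the PC9 and H2030 derivations by a test of the difference itself (adjusted p 5.05e-13 to 0.0478), 71 with a higher value in the PC9 derivation and 29 with a lower one. Many were named for a large change in one derivation or a large difference, so this share is higher by their choice; of all 15417 probe sets, 5662 differed. The values that follow are log2 differences, PC9 minus H2030.
Largest on the PC9 side were QPRT (9.60), FGB (7.69), FGG (7.57), HTATIP2 (7.24), FGA (6.40), PROCR (5.95), IGFBP7 (5.88), KRT13 (5.69), AKR1C2 (5.62), EPAS1 (5.61), VAMP8 (5.41) and IFI27 (5.30). Differences of 3 to 5 were found for ID4 (4.96), CHN1 (4.73), OAS1 (4.30), TUBB2B (3.9), JAG1 (3.81), GDF15 (3.65), MGP (3.64), AXL (3.47), KRT23 (3.46), CSTA (3.41), ENO2 (3.27), ROR1 (3.27), GADD45A (3.05) and EDN1 (3.04). Those of 2 to 3 were JUN (2.92), INHBA (2.91), INHBB (2.88), FOSL1 (2.68), JUP (2.64), HBEGF (2.58), CCL2 (2.57), TNFAIP8 (2.53), HK1 (2.50), GATA6 (2.45), DDB2 (2.33), CTSE (2.24), PFKP (2.10), ATF3 (2.09), S100A4 (2.04) and TNFAIP2 (2.01). Smaller ones were CDC6 (2.0), CCN1 (1.99), MCM10 (1.99), TGFBI (1.98), VIM (1.93), AP1M2 (1.92), DKK1 (1.83), ENC1 (1.75), HLA-F (1.74), ELF3 (1.56), IFI35 (1.56), AARS1 (1.45), PLOD2 (1.40), WNT5B (1.28), PMEPA1 (1.27) and CD44 (1.21), and the smallest CTSB (1.19), IDI1 (1.17), NSDHL (1.15), SNAI2 (0.97), IER3 (0.96), AEN (0.89), NEDD9 (0.83), PHLDA1 (0.80), ALDOC (0.77), PSPH (0.68), TMEM97 (0.67), ASNS (0.56) and TYMS (0.54).

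On the H2030 side the largest were CDH11 (-5.91), SCG2 (-5.68), TRIP6 (-5.55), PCDH7 (-5.11), S100A9 (-4.68), FN1 (-4.16) and SLPI (-4.14). They were followed by WNT5A (-3.79), DSP (-3.71), ADAMTSL3 (-3.54), S100A8 (-3.47), TRIB2 (-3.41), NEFL (-3.22), UPK3B (-3.11), ARID5B (-2.79), SLC1A3 (-2.76) and TCF7L1 (-2.73), and by OLFML3 (-2.50), DDIT4 (-2.36), MSLN (-2.29), CEBPD (-2.21), MUC1 (-2.17), MAP2 (-2.04), TTLL4 (-2.0), ITGB4 (-1.89), SFRP1 (-1.74), GPX3 (-1.0), FZD5 (-0.63) and MYC (-0.33).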

How the results depend on the processing

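The counts without H2030-BrM3 replicate 2 at a 2-fold threshold and the overlap of calls without it were chosen after its result was seen; the other alternatives were set before. Of 3454 values of genes and lists under processing alternatives, 3278 kept their direction and their side of the threshold, 153 fell below it, 8 passed it and 15 reversed; of 4960 with 1 array left out, these were 4637, 262, 18 and 43. Counts stayed within 1.5 times in 118 of 152 and 151 of 192. One probe set per gene, which tests fewer probe sets, gave 22 calls in the mean Wnt3A response, 10 in PC9, 0 in PC9-BrM3, 18 in H2030-BrM3, 2706 and 4010 for BrM3 in PC9 and H2030, 3665 for their mean, 3629 for their difference and 5732 for H2030 against PC9. With only the arrays of the comparison, which leaves fewer samples, Wnt3A counts were 11 in PC9, 0 in PC9-BrM3, 0 in H2030 and 1 in H2030-BrM3, and BrM3 in H2030 gave 3863. For the following the cause was not tested. Wnt3A counts in PC9, PC9-BrM3, H2030 and H2030-BrM3 (main 21, 4, 2 and 33) became 7, 5 and 57 in the last 3 with a pseudocount of 1, 2 and 1 in PC9-BrM3 and H2030 with 64 or with no filter, 10 in PC9 and 13 in H2030-BrM3 without the eBayes trend, and 40, 8 and 1 in PC9, PC9-BrM3 and H2030-BrM3 with array weights. The H2030 minus PC9 response (main 2) had 1 with median centring and 0 without the trend. Replicate numbers did not pair the arrays (28 pairs of groups, r -0.131 to 0.103, 1 over 0.1; 4 within a line, -0.079 to 0.103). As a replicate block they gave 2 in PC9-BrM3, and within line 12 in PC9, 1 in PC9-BrM3, 1 in H2030, 12 in H2030-BrM3 and 1 for H2030 minus PC9. Reversed values were all uncalled: CD44 with Wnt3A, -0.01 in the mean (quantile normalization, median centring), -0.01 in PC9 (median centring), 0.00 in PC9-BrM3 (quantile) and 0.00 in H2030 (median); MYC in H2030-BrM3 with Wnt3A -0.04 (median); CTNNB1 in PC9-BrM3 -0.02 and in the mean of both BrM3 lines 0.00 with the mean of the difference with and without Wnt3A, where CCND1 in H2030-BrM3 had 0.30 (0.01 with a pseudocount of 64); LEF1 in the BrM3 difference -0.57 (pseudocount of 1) and -0.07 (with and without Wnt3A); and in the BrM3 minus parental response BMP4 0.12 (pseudocount of 64) and LEF1 0.03 (64) and 0.02 (quantile). With 1 array left out, whose lone partner is assumed to vary like the other groups, counts ranged from 26 to 464 in the mean Wnt3A response, 10 to 27 in PC9, 0 to 7 in PC9-BrM3, 1 to 11 in H2030, 12 to 1812 in H2030-BrM3, 0 to 365 for BrM3 minus parental and 1 to 265 for H2030 minus PC9, the highest of 464, 1812, 365 and 265 all without H2030-BrM3 replicate 1. Those of BrM3 ranged from 2813 to 4943 in PC9, 4912 to 6497 in H2030, 4817 to 6346 for the mean and 4734 to 6235 for the difference, and H2030 against PC9 from 8023 to 9641. Values that reversed so ranged, with Wnt3A, for CD44 from -0.02 to 0.03 in the mean, -0.05 to 0.11 in PC9-BrM3, -0.02 to 0.07 in H2030 and -0.18 to 0.03 in H2030-BrM3; for CTNNB1 -0.04 to 0.02 in the mean, -0.15 to 0.07 in PC9 and -0.13 to 0.10 in H2030-BrM3; for MYC -0.09 to 0.12 in H2030-BrM3; and for the median of the mitotic list in H2030, the only called one, -0.101 to 0.029. For BrM3 they were CTNNB1 -0.07 to 0.16 in PC9 and -0.19 to 0.04 in the difference, and CCND1 -0.69 to 0.68 in H2030, -0.10 to 0.59 in the mean and -0.19 to 1.18 in the difference. For BrM3 minus parental they were BMP4 -0.32 to 0.24, CCND1 -0.06 to 0.62, LEF1 -0.25 to 0.16 and MYC -0.04 to 0.07, and for H2030 minus PC9 LEF1 -0.11 to 0.30. Signals under the 40th percentile of an array (55.2 to 68.68) lie near background, so fold changes of dim genes such as LEF1 and SCNN1A depend on the pseudocount.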

Other observations

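Genes of the lung epithelial lineage moved both ways in the BrM3 lines, and the list was called in neither. In H2030-BrM3 against H2030 the airway antiprotease SLPI (3.80) and the transcription factor CEBPD (1.93) rose while GATA6, a transcription factor of lung epithelium, fell (-1.98); 4 of 20 members were higher and 4 lower, also adjusted over the list alone (adjusted p = 0.981). In PC9-BrM3 against PC9 the ETS factor ETV5 rose (0.71) and the pioneer factor FOXA1 fell (-0.73), with 6 of 20 higher and 7 lower, 7 and 7 adjusted over the list alone (adjusted p = 0.811). Epithelial genes were likewise mixed. The desmosome gene DSP rose in H2030-BrM3 (2.99) and fell in PC9-BrM3 (-0.71), while plakoglobin, JUP (-2.76), and the epithelial adaptor subunit AP1M2 (-2.02) fell in H2030-BrM3, and the receptor ERBB3 (-0.95), ELF3 (-0.66) and MUC1 (-2.27) fell in PC9-BrM3. In H2030-BrM3 8 of 35 members were higher and 13 lower, 11 and 13 adjusted over the list alone (adjusted p = 0.322; median 0.036, mean -0.218, test downward), and in PC9-BrM3 3 were higher and 6 lower, 3 and 8 adjusted over the list alone (adjusted p = 0.316).

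Genes induced by p53, a list called in neither derivation, also held members that changed. In PC9-BrM3 the growth arrest gene GADD45A (1.82) and the nuclease AEN (1.44) rose, with 8 of 22 members higher and 1 lower, 8 and 2 adjusted over the list alone (adjusted p = 0.123). In H2030-BrM3 the stress cytokine GDF15 (-3.23) and the DNA damage binding protein DDB2 (-1.94) fell, with 4 of 22 higher and 6 lower, also adjusted over the list alone (adjusted p = 0.2).

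One hypothesis was that genes raised by Wnt3A lie higher in untreated BrM3 cells than in their parents; its 2 tests were chosen after the Wnt3A results were seen. Of 16 such genes, taken at their brightest probe set, 3 were higher and 4 lower in PC9-BrM3 (median -0.07, camera p = 0.534 with an estimated correlation), and 6 were higher and 6 lower in H2030-BrM3 (median 0.05, p = 0.402). BMP4 was higher in both lines (1.80 and 2.15) and EDN1 lower in both (-1.23 and -4.27), while TRIB2 rose by 4.03 and SGK1 fell by 2.21 in H2030-BrM3. These tests gave no support for the hypothesis and, with 16 genes, do not exclude it.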
